A study of Mus musculus with 9 samples.

How the data were processed

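ATAC-seq libraries of 3 mouse osteosarcoma cell lines were analysed, 3 per line, from the deposited narrowPeak lists. Per the submitters' processing notes, the tools included bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2, MACS2 2.1.0 and deepTools (version not given in the sources used here), with genome build GRCm38. Their settings, read filters, and any shift of reads for the Tn5 cut are not given in the sources used here. A missing shift would move peak edges by a few base pairs, which changes little in a comparison of overlapping peaks. The authors deposited 1 list per library, so replicates were not pooled. In the deposited lists each peak has a score, a fold ratio over local background at the summit, and -log10 p-value and -log10 q-value. These are the authors' values for that peak, and they were used only to rank or filter peaks within a list. The lowest -log10 q in the 9 lists was 1.3, so the threshold of the deposited lists was a q of 0.05.

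Read depth is unknown. The fold and p of MACS2 follow from a whole pile-up and a Poisson background at the summit, so both were solved for every peak. For very strong peaks, where the Poisson tail underflows, the tail was summed on a log scale. Tested on simulated data, this recovered 4848 of 4848 pile-ups exactly. The most frequent background in a library served as its relative depth, from 4.77 to 6.39.

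All lists were merged where peaks overlapped by 1 bp or more, and a region was called in a library that had a peak in it. A region was taken as specific to a line against another when it was called in 3 of 3 libraries of the first and 0 of 3 of the second. The gene table (RefSeq, GRCm38.p6, the same build) gives spans without strand, exons or sequence. The planned start sites were therefore replaced by gene ends: a gene was open in a library with a peak within 1000 bp of either end. For the same reason it was not stated whether a region is exonic or intronic. Regions were assigned to the protein-coding gene with the nearest end within 50000 bp. Motif tests need sequence and were not run.

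Counts of peaks and Jaccard indices were tested over all 280 partitions of the 9 libraries into 3 groups of 3. Gene lists, 24 fixed before the data were examined, were tested by the mean net regions per gene against 10000 random lists of the same size matched on deciles of regions per gene, with Benjamini-Hochberg adjustment over 72 tests and a threshold of 0.05. Named genes followed a rule fixed at the same time: Trp53, then per direction the 6 genes with the most net regions and the 6 strongest gene ends by the lowest percentile of -log10 q within the libraries, and up to 4 members of lists that passed or had 3 or more changed gene ends. Genes without a proper name were left out, and some items the rule names are not reported here. Osteoblast genes with large net values, and genes beside them in a run of missing calls, were named as examples from outside the rule after their values were seen.

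On data simulated for R172H against null, 200 of 200 implanted regions among 124230 were recovered, and 666 other regions were also called. The simulation used each region's call rate over all 9 libraries, so regions that differ between lines add to the 666. Of 40 random lists in 3 pairs, 2.5% of tests had p under 0.05, and 9 of 10 lists raised by 1 region per gene were called. Alternatives were a -log10 q of 5 or more, equal list lengths, summit windows of 250 bp either side, calls in 2 of 3 libraries, autosomes only, other gene end windows and assignment distances, the replicate block, and each library left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.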

Results

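Open chromatin was compared between 3 cell lines grown from primary mouse osteosarcomas, bone tumours, that differed in the p53 allele they carried. The R172H line had 1 copy of p53 with the R172H substitution and no other functional copy, the R245W line likewise carried R245W, and the null line had no p53 on either allele. Each genotype was represented by 1 line and by 3 ATAC-seq libraries, in which the Tn5 transposase cuts accessible DNA, so 9 libraries were available in all. The series title names distinct transcriptional programmes driven by different p53 mutants as the subject. Because every genotype had 1 line, a difference between genotypes is equally a difference between lines. The labels do not say whether the libraries of a line came from separate cultures. The p-values of tests that regroup libraries therefore measure the spread between libraries only, which may be technical. The gene list tests compare genes and the chromosome tests compare chromosomes, with the calls held fixed, so their p-values hold no spread between libraries. The values were the deposited peak lists, 1 per library. Read depth was unknown, and peaks were compared as called or not called.

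The p53-null line had the fewest peaks. It had 65638 ± 389 peaks per library (SD, n = 3), against 73366 ± 854 in the R172H line and 77202 ± 2075 in the R245W line. The spread of the 3 line means was larger than in any other grouping of the 9 libraries (exact permutation test over 280 partitions, one-sided p = 0.00357, the smallest possible). Between any pair of lines the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Peaks covered 51.4 ± 1.06 Mb in the null line, 55.6 ± 1.75 Mb in the R172H line and 61.2 ± 1.32 Mb in the R245W line (SD, n = 3). The share of peaks within 1000 bp of a gene end was 20.1% ± 0.0602 in the null line, 19.1% ± 0.108 in the R172H line and 18.9% ± 0.287 in the R245W line. The background pile-up recovered from the peak statistics, a relative measure of depth, was 5.41 ± 0.388, 4.98 ± 0.332 and 6.06 ± 0.376 in the same order. The null and R172H libraries overlapped in this measure, from 5.02 to 5.80 and from 4.77 to 5.36.

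Libraries of a line shared most of their open chromatin, and the R172H line stood apart from the others. The Jaccard index, the base pairs shared by a pair of peak lists over those covered by either, averaged 0.781 within lines and 0.507 between lines. The difference of 0.273 exceeded that of every other partition (exact permutation test, one-sided p = 0.00357). The null and R245W lines overlapped at 0.590, the R172H and R245W lines at 0.472 and the R172H and null lines at 0.460. Merging the lists gave 124230 regions, of which 36473 (29.4%) were called in all 9 libraries.

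**Figure D1:**
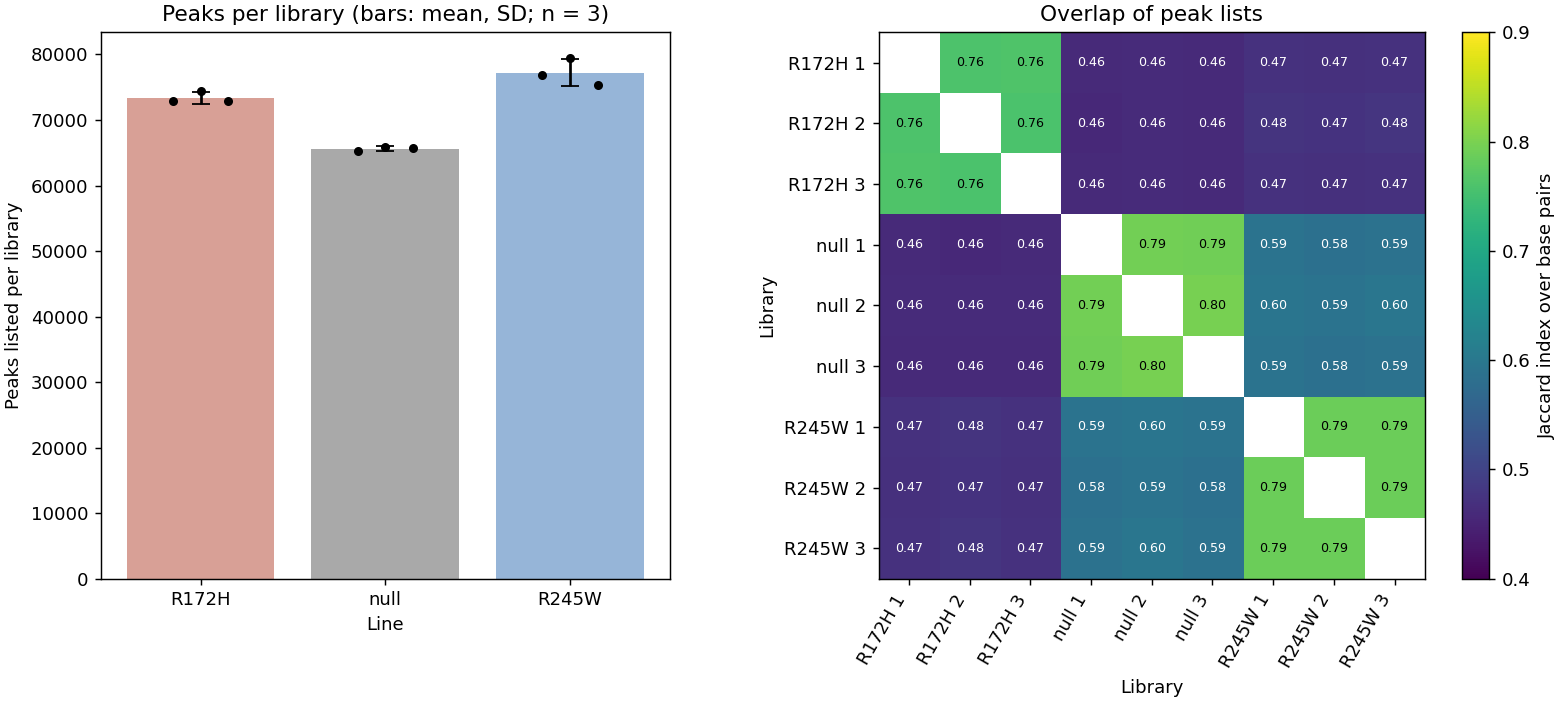
Left, peaks listed per library (y axis, count; points are libraries, bars the mean and error bars the SD, n = 3) for each line; right, the Jaccard index over base pairs for each pair of the 9 libraries, with the diagonal left blank. Libraries of a line overlap at 0.781 on average and libraries of different lines at 0.507.

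Trp53, the gene that encodes p53 (chromosome 11, 69580348 to 69591873, GRCm38), had an open gene end in all 9 libraries. A peak beyond its other end, listed at 69592011 to 69592707 in replicate 1, was called in all 3 null libraries and in none of the mutant libraries. It was weak, at percentiles of -log10 q of 10.8, 14.1 and 21.4 within the null libraries. The labels do not give the part of the gene removed in the null line, so these peaks do not check the labels.

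Comparing the R172H line with the null line asks what differs in open chromatin between cells carrying this mutant and cells with no p53. Genes with the most regions called in the R172H line alone included Gab1, an adaptor protein of receptor tyrosine kinase signalling, with 12 regions gained and 0 lost, and Aldh1a2, an enzyme of retinoic acid synthesis, with 9 gained and 0 lost. In the other direction Vipr2, a receptor for vasoactive intestinal peptide, and Zfhx4 each lost 9 regions and gained 0. A run of neighbouring regions missing from R172H reaches up to Zfhx4 (chromosome 3, 3719849 to 5215712). In total 18022 regions were called in all 3 R172H libraries and in no null library, and 12792 in the reverse direction. Of these, 6.35% and 4.73% lay at a gene end, against 30.5% of the regions called in all 6 libraries. Most were weak: the lowest percentile of -log10 q within the line's libraries had a median of 34.6 and 34.2, and exceeded 50 in 30.7% and 29.9%. When all lists were shortened to the same length the counts were 15438 and 14429. Libraries simulated without any difference between lines gave 695 regions called in R172H alone on average and 766 at most. Each was drawn independently, so simulated libraries of a line were no more alike than those of different lines. Call rates were taken per region over all 9 libraries, so regions that differ between lines add to the number. It is therefore not a measure of scatter between libraries alone, and it says nothing on genotype. No p-value is given per region, since an exact permutation test of 3 against 3 libraries cannot go below 0.1.

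At gene ends, 698 genes were open in all R172H and no null libraries and 279 in the reverse direction. Cdkn2b and Cdkn2a, neighbouring cell-cycle inhibitor genes, were open in the R172H line and had no peak at their ends in the null line. The peaks at these ends ranked at or above the 96.5 and 93.6 percentile of -log10 q in each R172H library. Both genes lie in 1 interval of 114 kb without a null peak, so they are not separate differences. Deletion and silencing cannot be told apart there. Other strong ends open only in R172H of this pair were those of Creld1 (96.9 percentile), Zfp46 (96.5), Tnp2 (94.7) and Hoxa5 (94.4). Runx3, a transcription factor of the Runx family, had an open end in all 3 null libraries (98.4 percentile or higher) and in no R172H library, and so did Adgrg1 (96.5), Catsper1 (91.6) and Cavin4 (91.6). Not every such end came with a specific region: Zfp46 and Tnp2 had 0 assigned regions in R172H alone, and Adgrg1 and Catsper1 had 0 in null alone. Creld1 had 1 in each direction. Cdkn2b had 3 and Hoxa5 1 in R172H alone, and Runx3 had 5 and Cavin4 3 in null alone.

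Among the gene lists fixed before the data were examined, the osteoblast lineage list came closest to a call in this pair. Its 22 genes with regions averaged -1.27 net regions per gene, against 0.170 in random lists matched on regions per gene (permutation test over 10000 random lists, two-sided p = 0.0014, adjusted p = 0.0504 over 72 tests), which misses the threshold of 0.05. Of these genes 4 had a net gain, 9 a net loss and 9 neither. Runx2, the central transcription factor of bone formation, stood at -5, and Dmp1, a bone matrix protein gene, at -5. Both lie at runs of neighbouring regions missing from R172H, of 4 regions at Runx2 and of 9 at Dmp1. The latter is shared with Sparcl1, Dspp, Ibsp and Mepe, so the losses at Dmp1 and its neighbours may not be separate. When the missing calls of R172H were shuffled, runs of up to 10 regions arose as well. The permutation test's adjusted p passed without null replicate 2 (0.0252), without R172H replicate 3 (0.0468) and without R245W replicate 1 (0.0336), the last only through the adjustment. It did not pass without R172H replicate 1 (0.132) or with equal list lengths (0.209), and over all alternatives the permutation test's adjusted p ran from 0.0072 to 0.209. No list passed in this pair in the main analysis. At gene ends, the osteosarcoma list of tumour suppressors and oncogenes had Cdkn2a, Cdkn2b and the receptor tyrosine kinase gene Kit open in R172H alone, and Pdgfra in null alone. The Wnt list had Wnt7b, Wnt2 and Dkk1 open in R172H and Wnt10b open in null. Wnt7b had 9 regions gained and 1 lost. Of the Hox list, Hoxa5, Hoxb3 and Hoxd11 were open in R172H, and Hoxd1 and Hoxd4 in null. Of the matrix list, Mmp3 and Fbn2 were open in R172H. Col6a3, a collagen gene, was open in null and had 9 regions in null alone against 2 in R172H alone. Wnt7b, Wnt2, Dkk1, Hoxa5, Hoxd11 and Fbn2 were also open in all R245W libraries, so they are ends missing from null. Hoxb3 and Mmp3 were open in no R245W library. Of the ends open in null, Wnt10b, Hoxd1 and Col6a3 were open in all R245W libraries too, and Hoxd4 in none. Several ends of these lists had weak peaks, with lowest percentiles of 17 at Dkk1, 15.1 at Pdgfra, 9.36 at Mmp3 and 7.28 at Hoxd1. Others were stronger, such as 79.7 at Wnt7b and 72.2 at Fbn2. Of the 30 p53 target genes, 28 had an open end in all 9 libraries, as did 22 of the 22 cell cycle genes. So did 18 of the 20 housekeeping genes and 12039 of all 21887 protein-coding genes, so this is not particular to p53 targets.

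**Figure D2:**
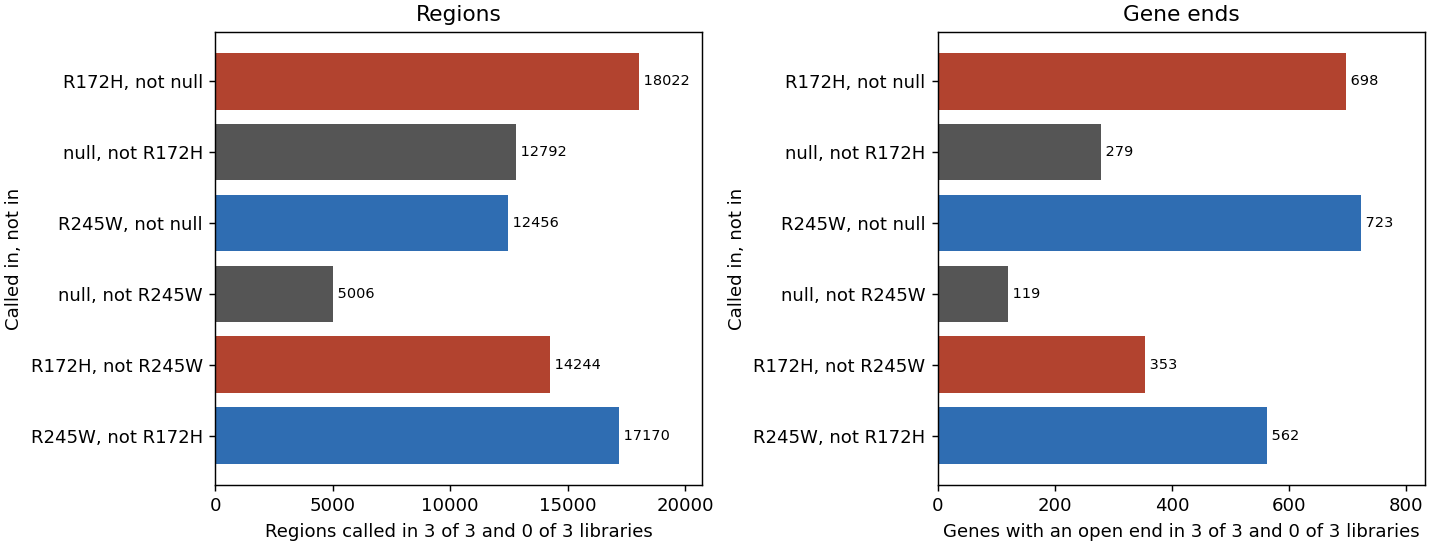
Counts for each ordered pair of lines, of regions (left, x axis) and of genes with an open end (right, x axis) called in all 3 libraries of the first line and in none of the second; bars are coloured by the line that has the call. The lowest counts in both panels are those of the null line against R245W, 5006 regions and 119 genes.

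Comparing the R245W line with the null line asks the same of the other mutant. Sash1 had 8 regions in R245W alone and 0 in null alone. Epb41l3, Zfp536, Aldh1a1 and Pax8 each had 7 and 0. Epb41l3 and Aldh1a1 lie at runs of 11 and 4 neighbouring regions missing from null, with 0 null peaks in either run. Pdzrn4 had 7 regions in null alone and 0 in R245W alone, and Vipr2 had 6 and 0. In all, 12456 regions were called in all R245W and no null libraries, and 5006 in the reverse direction. Most were weak, with a median lowest percentile of 26 and 23.6. Gene ends were open in R245W alone for 723 genes and in null alone for 119. With all lists shortened to the same length the region counts were 8771 and 7352 and the gene end counts were 567 and 210. The same Cdkn2b (99.1 percentile or higher) and Cdkn2a (86.1) ends were open in the R245W line. Zfp46 (99.1), Cyb561d1 (98.6) and Lrrc27 (95.3) were other strong ends. The strongest regions specific to R245W against null were those at or near Cdkn2b (99.1), Ccr1 (97.2) and Mga (93.7). The peaks at Zfp46, Cyb561d1 and Lrrc27 ranked above that near Mga, so they cannot lie in regions specific to R245W. An end with a peak within 1000 bp in 1 line alone is therefore not always a difference in regions.

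The limb and skeletal patterning list gained open regions in the R245W line relative to the null line. Its 43 genes with regions averaged 1.16 net regions, against 0.381 in matched random lists (permutation test, two-sided p = 0.0002, adjusted p = 0.0144), with 27 genes up, 3 down and 13 at zero. Hand2 and Six2, transcription factors of limb and skeletal development, had 2 regions gained and 0 lost each, and their gene ends were open in all 3 R245W libraries and no null library. Alx1 had the gene end alone, with a lowest percentile of 19.9. Foxf2, Barx2 and En1 each had 1 region in null alone. The call ended with lists of equal length (permutation test, adjusted p = 0.24) and when regions were assigned to the nearest gene span, an alternative chosen after seeing the data (adjusted p = 0.148). The permutation test's adjusted p over all alternatives ran from 0.0072 to 0.24. The Hox list had a mean of 0.526 against 0.219 (permutation test, p = 0.015, adjusted p = 0.216) and the matrix list -0.379 against 0.437 (p = 0.0043, adjusted p = 0.103), neither of which passed. The permutation test's adjusted p for the matrix list passed at an assignment distance of 20000 bp (0.0192), without R245W replicate 1 (0.0336) and when chromosome-adjusted, an alternative chosen after seeing the data (0.036). The smooth muscle and pericyte list had 4 gene ends open in R245W alone (Myocd, a cofactor of smooth muscle genes, Rgs5, Cspg4 and Abcc9) and the epithelial list another 4 (Trp63, Dsp, Grhl2 and Krt19), with none in null alone. Some of these ends had weak peaks. The lowest percentiles were 79.2, 35.1, 33 and 8.72 in the smooth muscle and pericyte list and 68.1, 53.9, 10.6 and 4.56 in the epithelial list, in the order named. Neither list's regions passed the test (permutation test, p = 0.159 and p = 0.635 before adjustment).

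**Figure D3:**
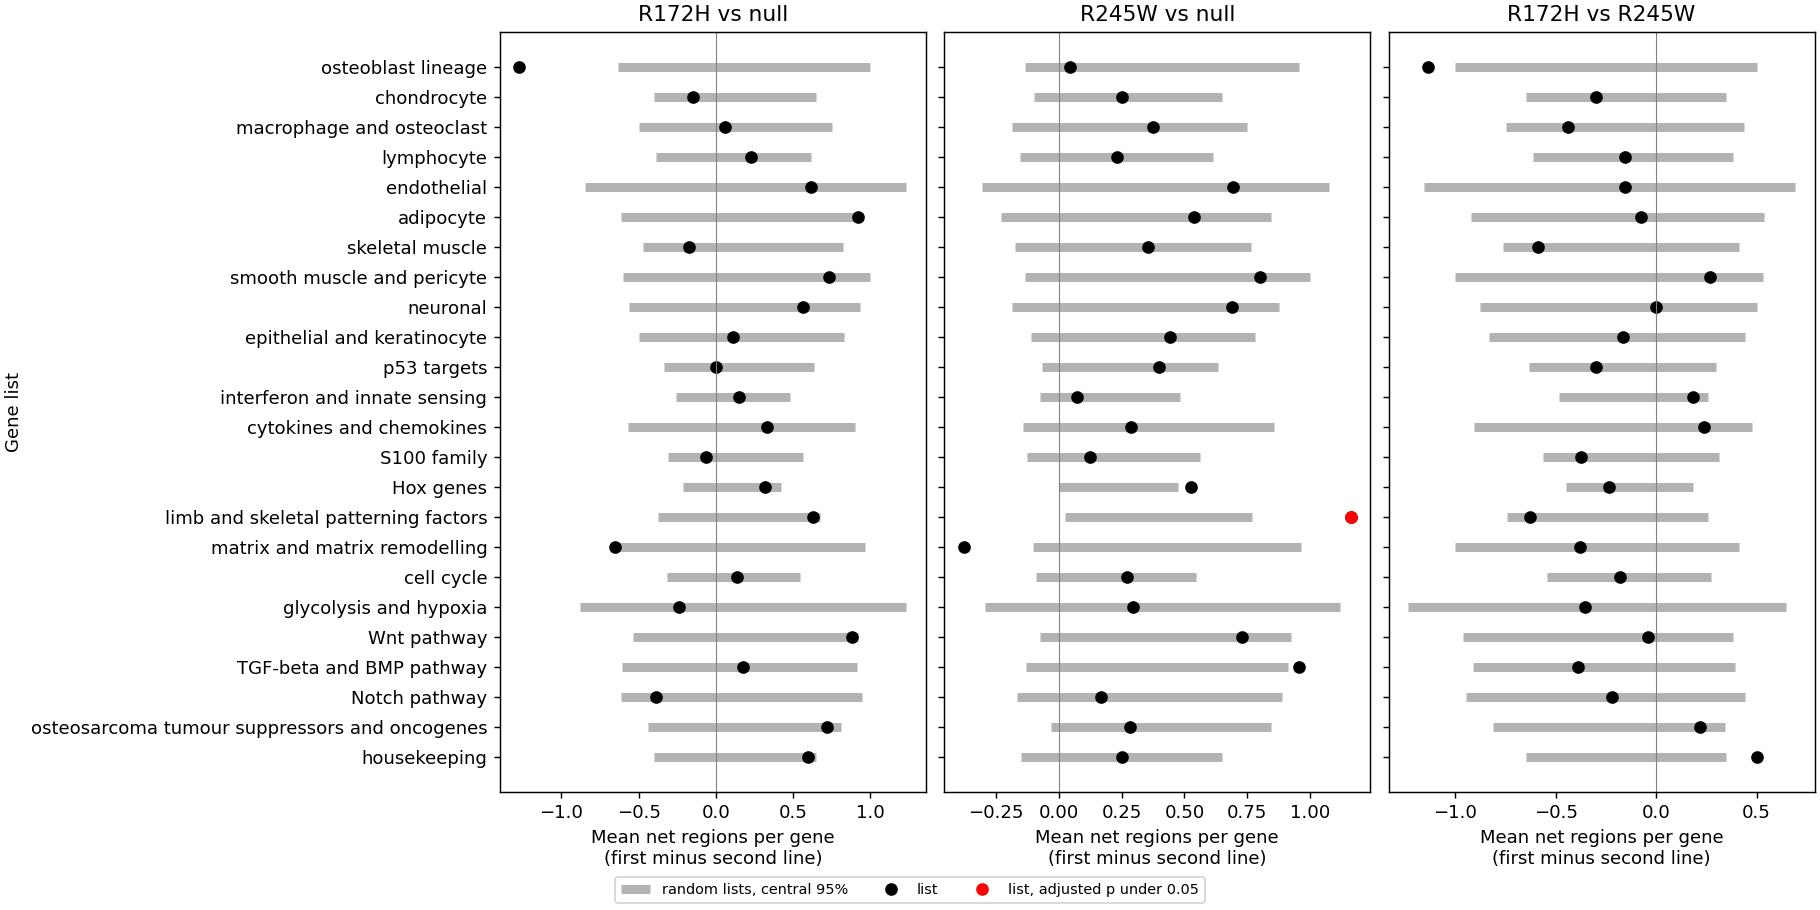
Mean net regions per gene (x axis, regions called in the first line alone minus those in the second line alone) for the 24 gene lists in the 3 pairs of lines, as dots, with grey bars for the central 95% of matched random lists. The limb and skeletal patterning list in R245W against null, at 1.16, is the only list with an adjusted p under 0.05.

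Comparing the mutant lines with each other asks whether the 2 mutations go with the same open chromatin. C1qtnf7 had 13 regions in R172H alone and 0 in R245W alone, and Igf2, an insulin-like growth factor gene, had 7 and 0. Zfhx4 had 10 regions in R245W alone and 0 in R172H alone, and Runx3 had 10 against 1. In all, 14244 regions were called in R172H alone and 17170 in R245W alone, with 353 and 562 gene ends. Here, as in the other pairs, alone means not in the other line of the pair, without regard to the third line. The lowest percentile of -log10 q within the line's libraries had a median of 32.9 and 32 in these regions. Dnajc5 (98.7 percentile), Dmac2l (95.4), Gpr173 (95.2), Tspyl2 (95.2) and Atl1 (94.2) were among the strongest ends open in R172H and not in R245W. Dnajc5, Dmac2l, Gpr173 and Tspyl2 were also open in all 3 null libraries (93.5 percentile or higher), so they are ends missing from R245W. The Dnajc5 peak ranked above the strongest region called in R172H and not in R245W (98.6, at Wt1), so it cannot lie in such a region. Not all of the ends open in R172H and not in R245W are separate differences: Dmac2l and Atl1 lie in an interval of chromosome 12 with no R245W peak, and Tspyl2 and Gpr173 at a run of missing R245W calls on chromosome X (152172308 to 152353090). Ends open in R245W and not in R172H were led by Cyb561d1 (98.6), Adgrg1 (96.7) and Lrrc27 (95.3). Adgrg1 was also open in all 3 null libraries (96.5), and Cyb561d1 and Lrrc27 in none. The Cyb561d1 peak ranked above the strongest region called in R245W and not in R172H (97.8), so it cannot lie in such a region. No list passed (osteoblast lineage: mean -1.14 against -0.258, permutation test, adjusted p = 0.289). At gene ends, the cytokines Il33 and Il1rn were open in R172H, and Lif, Cxcl2 and Cxcl5 in R245W. The matrix-degrading protease genes Mmp13 and Mmp3 were open in R172H (lowest percentiles 43.6 and 9.36) and Col6a3 in R245W (6.49).

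Regions called in all libraries of 1 line and in no other library numbered 22804, of which 12214 were in R172H, 7188 in R245W and 3402 in null. Regions called in both mutant lines and not in the null line numbered 3781. Independent lists of the same lengths, drawn from all 124230 regions, would share 1807. That reference is too low, since both lists can hold only regions with no null call, and null replicate 2 alone had 64821 regions called. Libraries simulated without any difference between lines gave 89.9 on average and 112 at most. Regions absent from both mutants and called in null numbered 3402, against 515 for independent lists and 147 for simulated libraries. The reference of 515 is too low in the same way, since those lists hold only regions called in all null libraries. The simulation drew each library independently, so libraries of a line were no more alike than those of different lines. Its call rates were those over all 9 libraries, so regions that differ between lines add to its counts. Both comparisons use the same null libraries, so either excess may come from them, and no sharing between the mutants can be read from it. The largest sharing between lines was not that of the mutants: 7717 regions were called in R245W and null and not in R172H, and 1066 in R172H and null and not in R245W.

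Several known tumour suppressor genes lay in intervals with no peak in 1 line. On chromosome 4 the null line had no peak between 89258356 and 89372304, an interval of 114 kb with Cdkn2a and Cdkn2b where the other libraries had 5 to 8 peaks each. On chromosome 11 the R245W line had none between 79264872 and 79494958, 230 kb that hold 1 end of Nf1, a negative regulator of Ras, where the others had 8 to 12. On chromosome 12 it had none between 69697238 and 70050266, 353 kb with Map4k5 and Sav1, a component of the Hippo pathway, where the others had 13 to 19. These 3 intervals were chosen after their values were seen. Coordinates are GRCm38.

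**Figure D4:**
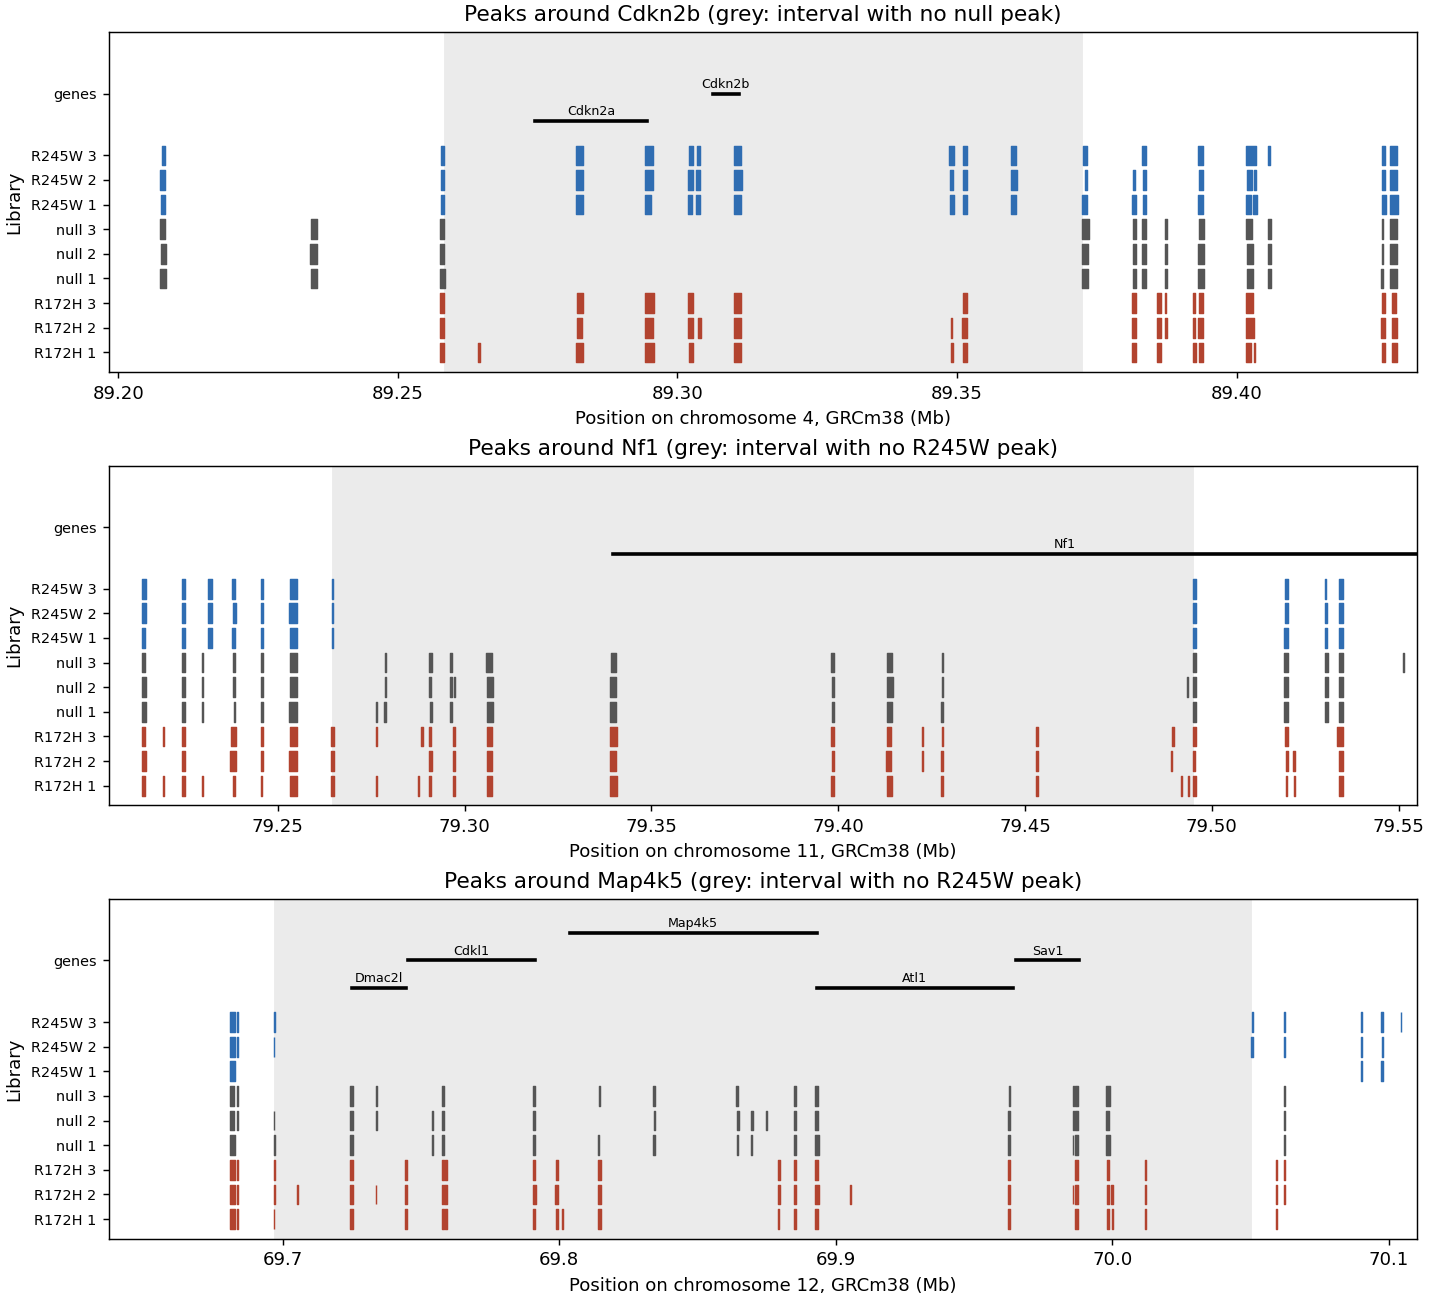
Peaks of each of the 9 libraries (rows, coloured by line) around Cdkn2b, Nf1 and Map4k5, with the spans of Nf1 and of genes wholly inside the interval as black bars above and the position in Mb on the x axis. Grey marks the interval in which the line named in the panel title has no peak, from 114 kb at Cdkn2b to 353 kb at Map4k5.

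Calls were spread unevenly over the chromosomes. On chromosome 8 the R172H libraries had 4264 ± 74.3 called regions, the null libraries 3127 ± 26.3 and the R245W libraries 3962 ± 88.9 (SD, n = 3). On chromosome 19 they had 2538 ± 32.6, 1802 ± 15 and 2409 ± 45.5, and on chromosome 18, 2304 ± 43.2, 2242 ± 31.6 and 1965 ± 52.2. The recovered pile-up at regions called in all 9 libraries, scaled by the library median, had a log2 ratio of R172H over null of 0.61 on chromosome 8 and of R245W over null of -0.67 on chromosome 18. The ratio of calls was not scaled for the total calls of a library, and R245W had more peaks than null. The signs of calls and pile-up can therefore differ without disagreement. For R245W over null on chromosome 4, calls stood at 0.13 and pile-up at -0.22. The list test that subtracts each chromosome's mean, chosen after seeing the data, kept the limb call (permutation test, adjusted p = 0.0216).

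**Figure D5:**
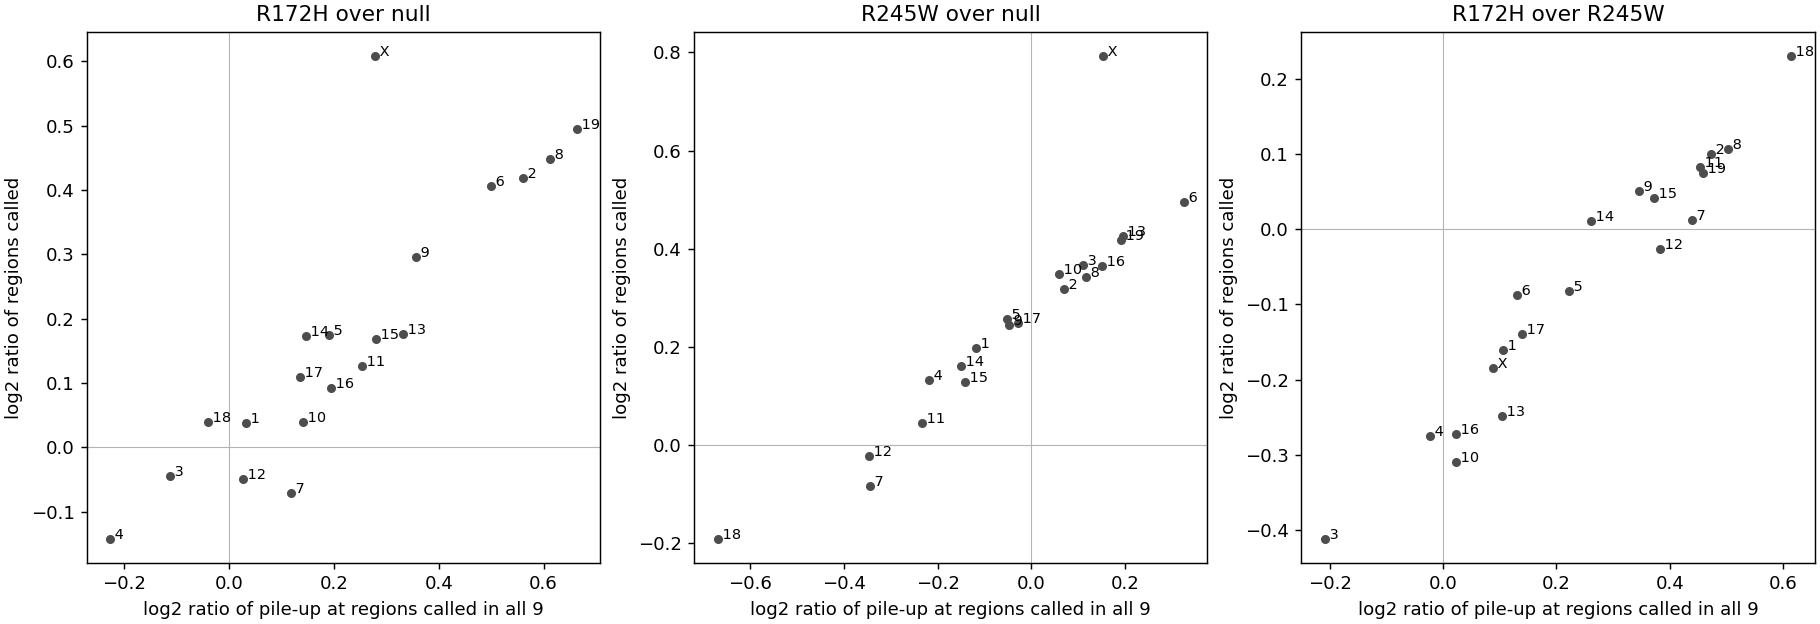
For each pair of lines, each point is a chromosome: the x axis is the log2 ratio of pile-up at the regions called in all 9 libraries, scaled by the library median, and the y axis the log2 ratio of regions called. Points rise together in each panel, with Pearson's r over 20 chromosomes of 0.855, 0.902 and 0.971 from left to right.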

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

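The alternatives named strong against none, chromosome-adjusted, nearest gene span and without missing runs were chosen after seeing the data. The 6 region counts of the pairs, the count unique to a line and the count shared by both mutants stayed within 1.5 times the main count under every alternative run, but equal list lengths brought the 2 directions closer: 15438 and 14429 for R172H against null, 8771 and 7352 for R245W against null. Of the gene end counts, only null against R245W moved, to 210 with equal list lengths. The number of list calls, 1 in the main analysis, was 0 with equal list lengths, 2 with a distance of 100000 bp, 3 with 20000 bp, 3 when chromosome-adjusted and 0 by nearest gene span, and ran from 1 to 3 with single libraries left out. The limb and skeletal patterning difference from random lists in R245W against null lost its call with equal list lengths (0.454 regions) and by nearest gene span (0.726), and ran from 0.787 to 0.835 with single libraries left out. The osteoblast difference in R172H against null passed at 100000 bp (-1.78), at 20000 bp (-1.13) and when chromosome-adjusted (-1.42), and ran from -1.56 to -1.25 with single libraries left out. It did not pass at the stricter threshold, with equal list lengths or by nearest gene span (permutation test, adjusted p = 0.144, 0.209 and 0.148). The cause of these shifts was not tested. The labels do not say that replicate numbers pair the libraries. Same-numbered libraries of different lines had correlations of -0.0013 to 0.0037 in the deviations of their calls from the line means. In every line, however, background pile-up was lowest in replicate 1 and highest in replicate 2, which also had the most peaks, so a shared processing by number stays open. Within the replicate block of 36 partitions, the exact permutation p for peaks per library was 0.0278, and the Jaccard difference was 0.273. No row for peaks per library exists with equal list lengths, which fix the count. The motif alternatives were not run. The Hox alternative changes only the Hox list. Unknown read depth limits all calls of absence.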

Other observations

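The tests below on peak number, chromosomes, runs of missing calls, region counts of the pairs and regions called in both mutants were chosen after the patterns were seen. The splits of the libraries for gene ends, for regions unique to a line and for the limb list were planned before their results.

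Some chromosomes had more calls in a line than others. On chromosome 8 the R172H libraries had 4264 regions on average and the null libraries 3127, and on chromosome 18 the R245W libraries had 1965 and the null libraries 2242. A candidate explanation is a difference in chromosome copy number, since extra copies give more reads at every site. Over 20 chromosomes the log2 ratio of regions called rose with the log2 ratio of pile-up at the regions called in all 9 libraries. Pearson's r was 0.855 for R172H against null, 0.902 for R245W against null and 0.971 for R172H against R245W, and Spearman's rho was 0.895, 0.97 and 0.973 (100000 permutations each, p = 1e-05 and adjusted p = 1e-05 over 3 relations, the smallest they can give). Without the 2 chromosomes farthest from the median, r was 0.806, 0.881 and 0.954. Chromosome X lay off the line in both comparisons with null, with log2 ratios of calls of 0.61 and 0.79 at pile-up ratios of 0.28 and 0.15, so copy number alone leaves part of its excess open. Chromosomes are not independent replicates, and a chromosome-wide change in accessibility would look the same, so biology stays open.

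Runs of 4 or more neighbouring distal regions, called in all 6 other libraries, were missing from a line more often than in shuffled orders. There were 102 runs in R172H, 75 in null and 5 in R245W, above the highest of 1000 shuffled orders (75, 12 and 3), an excess of at least 2. The shuffled orders averaged 50.9, 3.94 and 0.057 runs, so many of the R172H runs are expected without clustering. Shuffling ran over the whole genome, so differences between whole chromosomes can add runs. Deletion of every run in all cells is argued against, because the lines had calls at gene ends inside their runs: 30 of 38 in R172H, 26 of 47 in null and 2 of 8 in R245W, or at least 25% of them. Deletion of some runs stays open. Gene ends inside runs were missing more often than those outside: 21.1% against 3.33% in R172H, 44.7% against 3.4% in null and 75% against 0.43% in R245W. Of 59 runs that hold a gene end, 18 lacked every one. Silencing of a whole stretch would look the same. The Cdkn2b interval is not among these runs. It held 5 regions called in all 6 other libraries, 2 of them at gene ends, so fewer than 4 distal ones. The excess of runs therefore does not bear on Cdkn2a and Cdkn2b. At Cdkn2b, Nf1 and Map4k5, where 19 regions called in all 6 other libraries were absent, deletion and silencing cannot be told apart, because the deposited lists hold no reads outside peaks. Deletion may explain these intervals, as a hypothesis.

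The lower number of peaks in the null line was set against depth. Against R172H, lower depth is argued against: in each of 8 pairs of a null library and an R172H library of lower background pile-up the null library had fewer peaks, with a smallest difference of -6898, beyond the larger SD of 854. Weaker enrichment is argued against there too, since the lowest null library's median pile-up over background at shared regions was 2.02 above the highest R172H library's (larger SD 0.409). Against R245W both stay open. Only 1 R245W library was shallower than a null library (a difference of -10926 peaks), and the enrichment gap of 0.171 lay within the larger SD of 0.7. The difference of line and genotype stays open.

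For the counts of the pairs, 10 splits of 6 libraries are too few for a share under 0.05. In each pair 1 split, the real one, gave the largest count. Regions in both directions numbered 30814 for R172H against null (highest other split 180), 17462 for R245W against null (222) and 31414 for R172H against R245W (194). Gene ends numbered 977 (14), 842 (13) and 915 (15), and the limb list's distance from random lists was 0.783 (0.022). These gaps were fixed by design, because libraries of a line overlap and a split that mixes lines leaves few regions or gene ends. With so few regions no list can lie far from random lists, so the limb value is no support for its call. For regions unique to a line, 1 of 100 splits of the 280, the real one, gave 22804 (highest other 12330). Splits that mix lines give few such regions by design, because libraries of a line overlap. The count therefore shows that libraries of a line resemble each other, and cannot exclude chance differences between lines. For regions called in both mutants and not in null, setting each of 3 lines apart is too few for a share under 0.05. The real value was 3781 and 2 of the 3 choices gave as many, the highest other being 7717 with R172H set apart.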
